A study of Daphnia magna with 24 samples.

How the data were processed

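The water flea Daphnia magna was kept for 24 h in water collected at 4 sites of Greenhorn Mine in California, and whole-animal RNA was set against RNA of unexposed laboratory animals on 2-colour cDNA microarrays. Per the labels' protocols, the animals were adult females aged 14 to 16 days, exposures ran at 23.5 °C, and 10 to 15 animals were pooled for each exposure. The control animals stayed in COMBO, a defined freshwater culture medium. Per the labels, RNA was turned into aminoallyl cDNA and coupled to Cy3 or Cy5, and each exposure was hybridised on 2 arrays with the dyes exchanged. There were 4 sites, 3 exposures per site and 24 arrays in all. The design text states that the sites held different amounts of copper, and the amounts are not given in the sources used here.

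The deposited values are log ratios of both channels of an array, taken as log2. The base is not given in the sources used here. A base of 10 was ruled out because single values reached 6.15 and -6.16, beyond what a scanner's range allows, while the natural log stays possible, so that sizes and folds hold only if the base is 2. Scanner, background subtraction, spot filters and the authors' normalization are not given in the sources used here. The deposited array medians lay between -0.0359 and 0.0257, so the values had been centred or nearly so. Per array, 7015 to 7472 of 7680 features had a value, with 2.71% to 8.66% missing, and 5073 features had one on every array. No intensities were used here, so brightness and background cannot be weighed, and the number of exposures sets the precision.

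The direction of the ratio was worked out as far as the values allow. Both arrays of an exposure correlated positively in all 12 exposures, so the deposited dye-swap arrays already run one way. Dye bias gives the same check across exposures. Per exposure, the array with exposed RNA in Cy5 minus its partner, divided by 2, correlated positively in all 66 pairs of exposures (r from 0.28 to 0.757), so all exposures run one way. Arrays of one dye orientation gave r from -0.255 to 0.828 over 132 pairs. Whether a positive value means more or less RNA in exposed animals is not stated. Exposed over control is likely, because the design text compares field exposures with the control and the second channel holds exposed RNA, yet signs are given as positive and negative throughout.

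Each array was centred on its median and both arrays of an exposure were averaged, so that 1 exposure is 1 replicate. Features with a value in at least 2 of 3 exposures at every site were tested, which kept 7388 and left out 292. All 12 exposures entered one limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with 8 residual and 1.79 prior degrees of freedom. Each site mean was tested against 0, each of 6 pairs of sites was tested by a contrast, and a moderated F test asked for any difference between sites. Benjamini-Hochberg adjusted p under 0.05 within a comparison counted as changed. If a single control RNA served all exposures, the test against 0 leaves out the control's own spread. The labels do not say whether exposures came from separate cultures or shared control RNA. All exposures of a site carry the same source label, so separate water collections are not shown. The p-values thus measure the spread between these exposures, which may be partly technical and may leave out that between water collections. Tests against control also set field water against COMBO. Exposure numbers were checked as pairs by the correlation of deviations from the site means. Every same-numbered pair was over 0.1 for downstream 2 with upstream (lowest 0.233) and for downstream 1 with the entry (lowest 0.412). The main fit left all exposures unpaired. For these 2 comparisons a fit paired by number is given beside it, chosen from the data and not from the labels. What the numbers mark stays open. In the other 4 comparisons the lowest were -0.612, -0.439, -0.476 and -0.317. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

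The steps were tested on simulated data of 7388 features with the observed spread. For entry against control, limma called 40.3%, 68.7% and 93.9% of features with true log2 changes of 0.5, 1 and 2. These were 27, 46 and 62 true calls, beside 13 false calls. For entry against upstream the shares were 26.9%, 58.2% and 81.8%, also with 13 false calls.

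Features carry only array IDs. A table of Daphnia genes matched 0 of 7680 IDs, so the planned gene list tests and lists of other material could not be run, and no gene names appear. IDs start with A (2688 features) or P (4992). The rule for naming features, fixed before the data were examined, takes those past the threshold whose exposures all have one sign, or for a pair of sites do not overlap. Of these it names at most 2 with the largest positive and 2 with the largest negative difference in each comparison. Where nothing passed, the rule allows up to 3 features of lowest p in each direction as values, and 1 is given. It was picked only among features that meet the same condition of sign or overlap.

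Comparisons against control may share control RNA, which alone makes site responses similar. Unchanged sites sharing controls were therefore simulated 100 times, with overlaps of calls fitted in 20 of them. Controls were shared by exposure number, and control and exposure were each given an equal part of the observed variance. This assumed split fixes the simulated r in advance. Alternatives fixed before the data were examined were no centring, scaling to one median absolute deviation, stricter and looser filters, a fit of all 24 arrays with a dye term and the exposure as a random block, arrays of one dye orientation, array weights, a robust spread, a fit of the compared groups alone, the exposure number as a block, and each exposure left out in turn.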

Results

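The data are log ratios between exposed and unexposed Daphnia magna, a freshwater crustacean, measured on 24 arrays. They are taken as log2, though the base is not given, and whether positive means more RNA in exposed animals is not stated. The 4 groups of 3 exposures were compared, with water from upstream of the mine, from the point where mine drainage enters, and from a first and a second downstream position, called downstream 1 and downstream 2. The last 3 are called mine-water sites here. Between 7015 and 7472 features had a value on an array.

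Both dye-swap arrays of an exposure correlated across features with a mean r of 0.572, from 0.149 in upstream exposure 3 to 0.772 in downstream 2 exposure 3. Features are not independent replicates, so these r values only describe the arrays. A dye effect passed limma's threshold in 4155 of 7387 features (56.2%), with a median size of 0.12, and cancels where both orientations are averaged. Exposures of one site correlated with a mean r of 0.393 at the entry, 0.489 at downstream 1 and 0.505 at downstream 2. The 3 upstream exposures gave a mean of -0.116. The median feature's SD between exposures was 0.259 upstream, 0.174 at the entry, 0.151 at downstream 1 and 0.205 at downstream 2. The widest spread was therefore upstream.

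**Figure D1:**
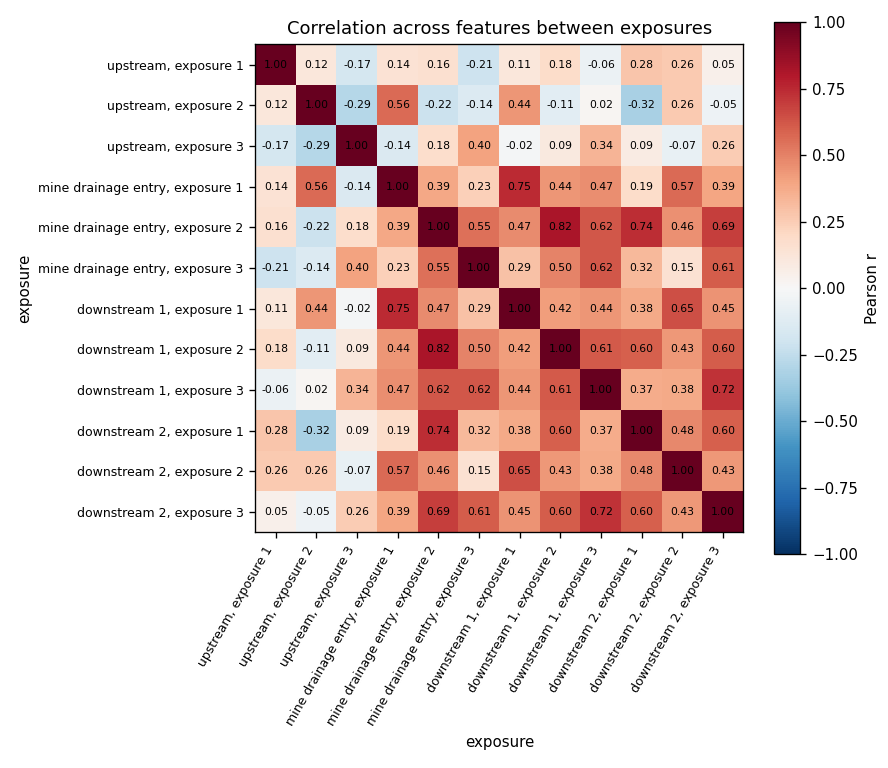
Pearson correlation across features (colour, no unit) between all 12 exposures, each the mean of 2 dye-swap arrays. Mine-water exposures correlate positively with each other, while the upstream exposures correlate with each other between -0.288 and 0.115.

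Upstream water against control asked how far expression in water from above the mine differed from that in COMBO. None of 7388 features changed in limma at an adjusted p under 0.05, and 480 had an unadjusted p under 0.05. The lowest adjusted p was 0.46. It belonged to A5P3, with a log2 ratio of 2.13 ± 0.48 (SD, n = 2), the positive feature of lowest p. Among negative features with one sign in all upstream exposures, A7I8 had the lowest p, at -0.42 ± 0.22 (SD, n = 3, limma adjusted p 0.77). The 95% interval of a site mean, not adjusted for the number of tests, reached 0.3 to either side for the median feature. Passing the adjusted threshold took more. In the simulated data, 40.3% of true changes of 0.5 and 68.7% of those of 1 were called for entry against control. The simulated spread was the same at all sites, so fewer may be called upstream. Upstream changes well over 0.3 may therefore have been missed. With arrays of exposed RNA in Cy5 alone 163 features passed, and with Cy3 alone 0. The dye effect does not cancel in either, and whether it gave the 163 was not tested.

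With water from the mine drainage entry, 405 features were changed against control, 196 positive and 209 negative, which is 5.48% of those tested. Their median size was 1.09 on the log2 scale, and 222 exceeded 1. The largest positive value was that of P8BB11, at 4.13 ± 1.21 (SD, n = 3; limma adjusted p 0.00074), a 17.5-fold ratio, against 0.63 ± 0.47 upstream. P4CB5 followed at 4.11 ± 1.25 (adjusted p 0.0024). The largest negative values were those of P13DA2, at -2.41 ± 0.95 (adjusted p 0.014), and P9AG7, at -2.30 ± 1.02 (adjusted p 0.026). P13DA2 no longer passed without entry exposure 2 (-1.87), and P9AG7 without any 1 of the 3 (-2.67 to -1.72). The count was 230, 144 and 274 without entry exposure 1, 2 and 3, 699 in a fit of all 24 arrays and 726 with array weights. With arrays of exposed RNA in Cy5 alone it was 609, and no feature passed when the entry's 3 exposures were fitted alone (968 at an unadjusted p under 0.05).

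With water from downstream 1, 237 features were changed against control, 158 positive and 79 negative, with a median size of 0.96. P4CB5 was at 3.62 ± 1.00 (SD, n = 3; limma adjusted p 0.0068) and P11CH10 at 3.48 ± 1.02 (adjusted p 0.0025). The largest negative values were -2.23 ± 0.13 for P11CC4 (adjusted p 2.8e-05) and -2.16 ± 0.75 for P13DA2 (adjusted p 0.034). P11CC4 stood at 0.17 ± 0.15 upstream. P4CB5 no longer passed without downstream 1 exposure 2 or 3 (3.41 and 3.26) or with scaled arrays (3.77), nor P13DA2 without any 1 exposure of this site (-2.50 to -1.76) or with exposed RNA in Cy5 alone (-1.52). Without downstream 1 exposure 1, 2 and 3 the count was 119, 78 and 99. It was 152 with scaled arrays, 477 with all 24 arrays, 653 with array weights, 360 and 1217 with exposed RNA in Cy5 or Cy3 alone, and 9 with this site fitted alone.

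With water from downstream 2, 492 features were changed against control, 260 positive and 232 negative, with a median size of 0.95. P4CB5 was at 3.69 ± 0.92 (SD, n = 3; limma adjusted p 0.0044) and P8BE5 at 3.67 ± 0.80 (adjusted p 0.0011). P13DA2 reached -3.02 ± 1.08 (adjusted p 0.004) and P9AG7 -2.69 ± 1.26 (adjusted p 0.011). Without downstream 2 exposure 1, P4CB5 (3.22) and P9AG7 (-1.97) no longer passed. The count was 157, 262 and 446 without downstream 2 exposure 1, 2 and 3, 769 with all 24 arrays and 741 with array weights. It was 836 with exposed RNA in Cy5 alone, and 0 with this site fitted alone (1074 at an unadjusted p under 0.05).

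**Figure D2:**
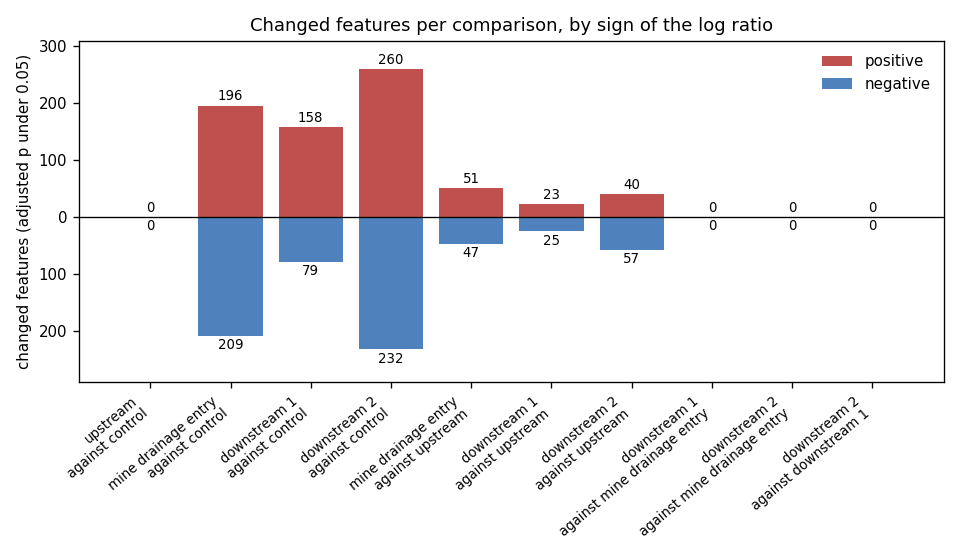
Number of features past an adjusted p of 0.05 in limma (vertical axis) in each of 10 comparisons, with positive log ratios above 0 and negative ones below. Entry, downstream 1 and downstream 2 had 405, 237 and 492 changed features against control, upstream had 0, and the 3 mine-water sites had 0 between them.

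The sites were next set against the upstream site, because they were said to differ in copper. Entry water differed from upstream water in 98 features, 51 positive and 47 negative, with a median size of 1.38. The largest positive differences were 3.65 for P3CB12 (SE 0.57, limma adjusted p 0.022) and 3.58 for P11CH10 (SE 0.64, adjusted p 0.03). The largest negative differences were -2.53 for P13CD12 (SE 0.39, adjusted p 0.021) and -2.19 for P11CC4 (SE 0.19, adjusted p 0.00072). With scaled arrays none of these 4 passed, though they were at 3.97, 3.88, -2.61 and -2.27. P11CC4 passed without each exposure in turn (-2.35 to -2.00). P3CB12 (3.20 to 4.32) and P11CH10 (3.03 to 4.25) passed only without entry exposure 1, and P13CD12 (-2.84 to -2.27) only without that one or upstream exposure 3. With scaled arrays 58 features passed, 19 of them positive (32.8%, against 52% here). Without upstream exposure 1, 2 and 3 the count was 15, 14 and 52, and without entry exposure 1, 2 and 3 it was 64, 20 and 41. It was 372 with all 24 arrays, 62 with array weights, 52 with exposed RNA in Cy3 alone and 7 with both sites fitted alone.

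Downstream 1 differed from upstream in 48 features, 23 positive and 25 negative. P9CF4 and P8CB10 had the largest positive differences, 3.19 and 3.18 (SE 0.55 each, limma adjusted p 0.037 each). P11CC4 had the largest negative one, -2.40 (SE 0.19, adjusted p 0.00036), and P13CD12 followed at -2.26 (SE 0.39, adjusted p 0.037). With scaled arrays none of these 4 passed, though they were at 3.29, 3.32, -2.39 and -2.18, and with exposed RNA in Cy5 alone P8CB10 (3.15) and P13CD12 (-2.12) did not. P11CC4 passed without each exposure in turn (-2.48 to -2.33), and P9CF4 (2.95 to 3.64) and P8CB10 (2.87 to 3.62) only without downstream 1 exposure 1. P13CD12 failed each time (-2.53 to -2.00). With scaled arrays 9 features passed, 9 of them positive (100%, against 47.9% here), so the balance of signs depended on the scaling. The count without upstream exposure 1, 2 and 3 was 10, 9 and 25, and without downstream 1 exposure 1, 2 and 3 it was 45, 9 and 13. Other settings gave 194 with all 24 arrays, 28 with array weights, 26 with exposed RNA in Cy5 alone and 16 with both sites fitted alone.

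Downstream 2 differed from upstream in 97 features, 40 positive and 57 negative. The largest positive differences were 3.49 for P8BE5 (SE 0.60, limma adjusted p 0.027) and 3.44 for P3CB12 (SE 0.57, adjusted p 0.025). P13CD12 differed by -2.82 (SE 0.39, adjusted p 0.014) and P11CC4 by -2.71 (SE 0.19, adjusted p 0.00011). With scaled arrays P11CC4 passed (-2.84), and P8BE5 (3.68), P3CB12 (3.63) and P13CD12 (-2.89) did not. P11CC4 also passed without each exposure in turn (-2.84 to -2.59), while P3CB12 failed each time (3.14 to 3.70). P8BE5 (3.07 to 3.86) passed only without downstream 2 exposure 2. P13CD12 failed without upstream exposure 1 or 2 or downstream 2 exposure 1 (-2.82, -2.56 and -2.54). The count was 11, 11 and 48 without upstream exposure 1, 2 and 3, and 16, 41 and 60 without downstream 2 exposure 1, 2 and 3. It was 55 with scaled arrays, 411 with all 24 arrays, 32 with array weights, 157 and 39 with exposed RNA in Cy5 or Cy3 alone, and 25 with both sites fitted alone. With the exposure number as a replicate block as well, both sites alone gave 0 (963 at an unadjusted p under 0.05), a fit with 2 residual degrees of freedom.

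The 3 mine-water sites were then compared with each other. No feature passed limma's threshold for downstream 1 against the entry (41 at an unadjusted p under 0.05), downstream 2 against the entry (253) or downstream 2 against downstream 1 (262). Each of these counts is below what chance alone would give at that p over 7388 features. These unpaired tests thus appear conservative, and the counts of 0 do not show that the sites were alike. Paired by number and with both sites alone, downstream 1 against the entry also gave 0, with 349 at an unadjusted p under 0.05. The 95% interval of a difference reached 0.42 to either side for the median feature. It used the spread pooled over all 4 sites and was not adjusted for the number of tests. In the simulated data, 26.9% of true changes of 0.5 and 58.2% of those of 1 were called for entry against upstream. Differences well over 0.42 may therefore have been missed. A6E16 had the lowest p among negative differences without overlap of the exposures, in both comparisons with the entry. It was at 0.02 ± 0.03 upstream, -1.49 ± 0.15 at the entry, -1.79 ± 0.05 at downstream 1 and -2.01 ± 0.08 at downstream 2 (SD, n = 3). The steps of -0.30 and -0.52 from the entry did not pass (limma adjusted p 1 and 0.81). P11AF9 was at -1.77 ± 0.14 at the entry and -0.99 ± 0.15 at downstream 1, a difference of 0.78 (adjusted p 1). A5I7 was at 1.39 ± 0.78 at downstream 2 and -0.59 ± 0.33 at the entry (adjusted p 0.81). Between the downstream sites A5I11 differed by 1.64 and P9BF6 by -0.43 (adjusted p 1 each). Over all 4 sites at once, the F test called 42 features, and 577 had an unadjusted p under 0.05. Without upstream exposure 1, 2 and 3 it called 9, 10 and 17. The count was 45, 18 and 13 without entry exposure 1, 2 and 3, then 48, 10 and 31 without those of downstream 1, and 17, 20 and 21 without those of downstream 2. Scaled arrays gave 10, array weights 18 and all 24 arrays 335.

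**Figure D3:**
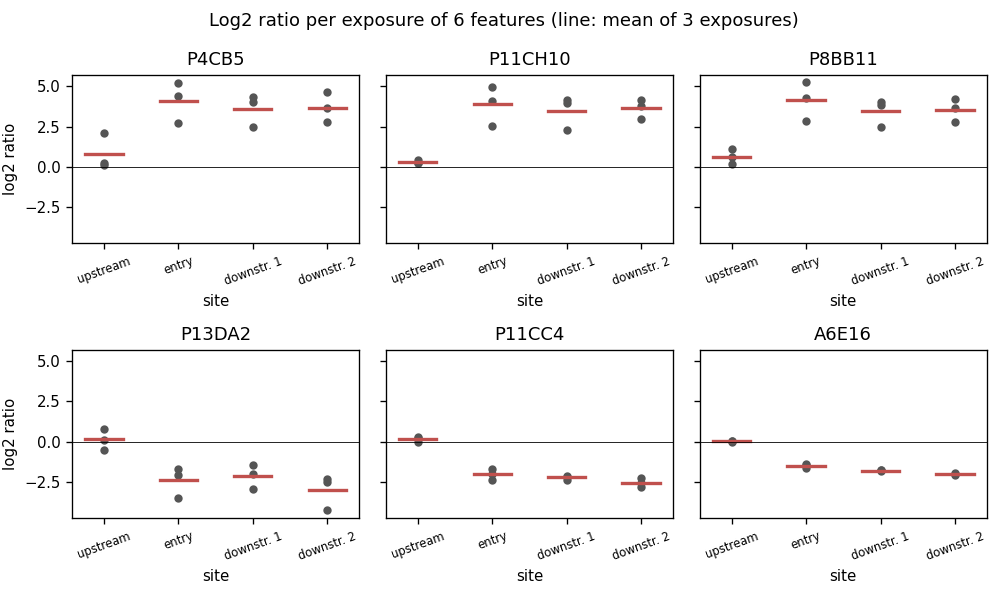
Log2 ratio against control (vertical axis) of 6 named features in each exposure (points) at 4 sites (horizontal axis), with lines at the site means. P4CB5, P11CH10 and P8BB11 are positive at the mine-water sites and P13DA2, P11CC4 and A6E16 negative, and A6E16 is at 0.02 upstream and -2.01 at downstream 2.

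The mine-water sites shared many of their changed features. Of 607 features changed against control at 1 or more of these sites, 254 were changed at 1 site, 179 at 2 and 174 at all 3. All 174 had one direction, 101 positive and 73 negative. Entry and downstream 1 shared 203 calls, against 6.42 for independent lists of those sizes. Entry and downstream 2 shared 310, against 13.5, and both downstream sites shared 188, against 8.04. No feature was called in opposite directions. Unchanged sites with shared controls gave at most 0.1 shared calls on average in simulation, but such sites yield almost no calls. This value therefore does not tell how many of the shared calls came from shared controls, nor do the values for independent lists. The 174 became 376 with all 24 arrays, 342 with array weights, 303 with exposed RNA in Cy3 alone and 0 with each site fitted alone. Without downstream 1 exposure 1, 2 and 3 they became 107, 74 and 87. Calls shared by pairs of sites moved both ways. Entry and downstream 1 shared 406 with all 24 arrays, 433 with array weights and 378 with exposed RNA in Cy3 alone. Entry and downstream 2 shared 530 with all 24 arrays, 476 with array weights and 468 with exposed RNA in Cy5 alone. The downstream sites shared 385, 371, 296 and 483 with all 24 arrays, array weights, Cy5 alone and Cy3 alone. Fewer were shared with an exposure left out. Entry and downstream 1 shared 129 without entry exposure 2, and 113, 76 and 89 without downstream 1 exposure 1, 2 and 3. Entry and downstream 2 shared 193 and 133 without entry exposure 1 and 2, and 145 without downstream 2 exposure 1. The downstream sites shared 111, 76 and 97 without downstream 1 exposure 1, 2 and 3, and 118 without downstream 2 exposure 1. With each site fitted alone, 0 calls were shared by any of these pairs.

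The features called at the entry were followed at the other sites. Of these 405, 404 had the same sign at downstream 1 and 401 at downstream 2, with slopes of 0.82 and 0.92 on the entry means. Upstream, 232 had that sign (57.3%), the slope was 0.05, and their median size was 0.13. The features were chosen at the entry, which favours large values there. The choosing site was not always the largest. The 237 features called at downstream 1 had a median size of 1.03 at the entry and 0.96 at downstream 1. The 492 called at downstream 2 had 0.80 at the entry and 0.95 at downstream 2.

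**Figure D4:**
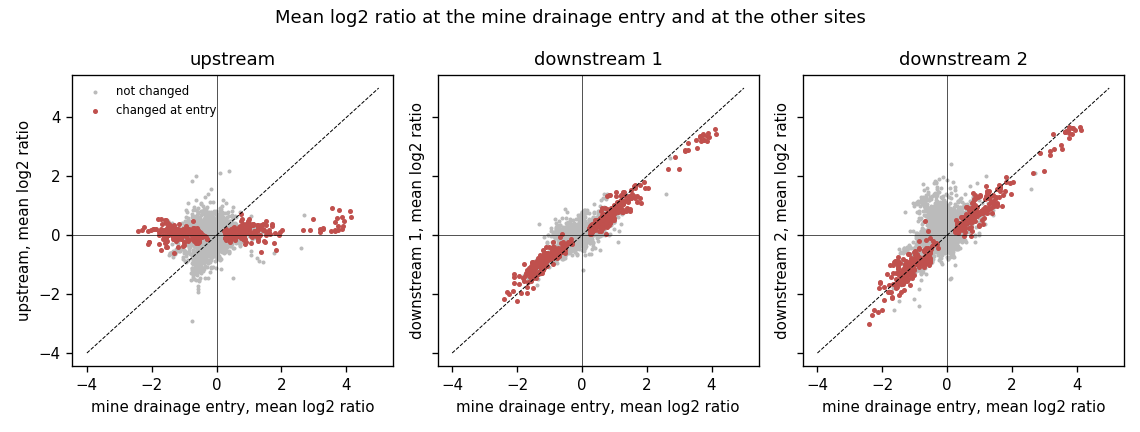
Mean log2 ratio against control of each feature at the entry (horizontal axis) and at upstream, downstream 1 and downstream 2 (vertical axes), with the 405 features changed at the entry in red and a dashed line of equal values. The red points lie near the dashed line at both downstream sites (slopes 0.82 and 0.92) and near 0 upstream (slope 0.05).

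Over the 174 features shared by all mine-water sites, the mean log2 ratio, with negative features turned, was 1.43 ± 0.23 at the entry, 1.27 ± 0.16 at downstream 1, 1.33 ± 0.14 at downstream 2 and 0.11 ± 0.11 upstream (SD, n = 3). These features were chosen at the mine-water sites, so their distance from upstream is no independent evidence. The unpaired tests between mine-water sites did not pass. Downstream 1 minus entry was -0.16 (exact permutation p 0.4, two-sided), downstream 2 minus entry -0.09 (exact p 0.7) and downstream 2 minus downstream 1 0.06 (exact p 0.7). With 3 exposures a side the smallest possible p is 0.1. Same-numbered exposures of the entry and downstream 1 deviated together, and paired by number downstream 1 was lower in 3 of 3 pairs, by -0.12, -0.29 and -0.06 (exact sign-flip p 0.25, the smallest 3 pairs allow). Leaving out 1 exposure moved this difference between -0.273 (without entry exposure 1) and -0.04 (without entry exposure 2), with -0.062 without downstream 1 exposure 1. Downstream 2 minus entry became -0.21, 0.023, -0.174 and -0.037 without entry exposure 1, entry exposure 2, downstream 2 exposure 1 and downstream 2 exposure 2. Downstream 2 minus downstream 1 became -0.032, 0.114, 0.108, -0.017 and 0.12 without downstream 1 exposure 1, 2 and 3 and downstream 2 exposure 1 and 2, so neither sign held.

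**Figure D5:**
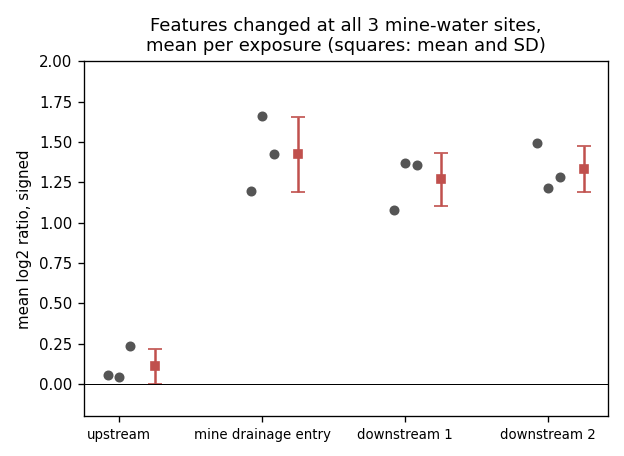
Mean signed log2 ratio of the 174 features changed at all 3 mine-water sites, per exposure (grey points) and as mean and SD of 3 exposures (red). Mine-water exposures lie between 1.08 and 1.66 and upstream exposures between 0.04 and 0.23.

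Across all tested features, site means correlated with r = 0.884 between entry and downstream 1, 0.693 between entry and downstream 2 and 0.741 between the downstream sites. Sharing controls alone gave 0.489, 0.483 and 0.486 in simulation. These values follow from the assumed equal split of the variance between control and exposure. They do not estimate what shared controls contributed here, so distances from the simulated values are description only. The covariances were 0.1359, 0.1344 and 0.1206, and lay 0.1069, 0.1056 and 0.0917 above the simulated ones. Upstream correlated with these sites at 0.158, 0.219 and 0.168, below the simulated 0.488, 0.489 and 0.482. Leaving out 1 exposure took them as low as -0.06 (without entry exposure 1), 0.079 (without downstream 1 exposure 1) and -0.024 (without upstream exposure 1). Arrays with exposed RNA in Cy3 alone, which keep the dye effect that the exposures share, gave 0.372, 0.467 and 0.307. Features on all 24 arrays gave 0.187, 0.188 and 0.004. Single exposures of different numbers correlated with means of 0.472, 0.486 and 0.514 among mine-water sites, and of 0.068, 0.109 and -0.01 between upstream and them. Different numbers do not rule out shared control RNA, because some exposures of different numbers also deviated together. Part of any similarity may come from shared control RNA, since the labels do not say whether it was shared.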

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

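The tests of the sets of exposures and of the upstream site below were chosen after the result was seen, as were the splits by pairs and the look at single groupings, while the other splits were planned before. Each site was set against the same kind of control, and 4 results differ between sites by a test of the difference itself. Entry water differed from upstream water in 98 features, downstream 1 in 48 and downstream 2 in 97. The F test over all sites called 42.

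For a pair of sites, 3 exposures against 3 allow 10 splits, too few for a share under 0.05. The real splits gave 98, 48 and 97 features for entry, downstream 1 and downstream 2 against upstream, and the highest other splits gave 0, 0 and 1. Among the mine-water sites the real splits gave 0 and the highest others gave 0. No split can give fewer than 0, so 10 of 10 splits gave as many in each of these 3 pairs by construction. Against control, turning the sign of 1 exposure gives 4 patterns, again too few. The real counts of 405, 237 and 492 stood against a highest other of 0 each. For upstream the real count of 0 stood against 5, so 4 of 4 patterns gave as many, again by construction. For the F test, 3 of 100 groupings of the 12 exposures, the real one included, gave at least 42 features. The highest other grouping called 222, several times the real count, which points to another structure among the exposures. The sets described next do not account for it alone: 8 of its 12 pairs of exposures placed together were of one set, yet 3 other groupings with 8 such pairs called 3, 0 and 0. The next highest called 197, with 5 such pairs, and kept the 3 upstream exposures together. Free groupings ignore these sets, and only 6 of the 100 put no pair of one set together, as the real one does. Among 100 of the 576 groupings that do so, drawn after the sets were seen, only the real one gave at least 42. The highest others gave 40 and 37. The 3 others that kept the upstream exposures together, these included, were the only ones with a call. For downstream 2 against upstream, where same-numbered exposures deviated together, the 3 other splits that part all 3 pairs called 0, against 97. For downstream 1 against the entry these splits called 0, as did the real one.

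The first pattern is that the deviations of exposures from their site means fell into 3 sets across sites. One set joins upstream exposure 2, entry exposure 1, downstream 1 exposure 1 and downstream 2 exposure 2. Another joins upstream 1, entry 2, downstream 1 exposure 2 and downstream 2 exposure 1, and the last joins exposure 3 of every site. Array or dye noise is argued against by a mean r of 0.386 within sets (lowest 0.024) with only arrays of opposite dye orientation paired. Effects shared by all features of an ID prefix are argued against by a mean r of 0.431 with prefix means removed. The sets were found in averages of these same arrays, which can raise both values. The rank across dyes, given next, is free of that choice. A shared control sample or a shared day may underlie the sets: the mean r within sets was 0.479, against 0.328 for the next best of 216 matchings, and the matching found on Cy5 arrays ranked 1 of 216 on Cy3 arrays. Control and day were not separated, and the exposure numbers of the labels follow these sets only for some pairs of sites (mean r 0.1 by number, rank 36), so no set was used as a block. Numbers 1 and 2 exchanged at upstream and downstream 2 would give these sets exactly. Whether that happened or the numbers mark nothing shared stays open. Same-numbered exposures are of one set for downstream 2 with upstream and for downstream 1 with the entry, and not for the block over all sites.

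The second pattern is that the mine-water sites had changed features against control and upstream had none. A control sample shared by all sites that was itself unusual would move them alike, yet over the 405 features changed at the entry the slope of the upstream means on the entry means was 0.046. It was 0.106 and 0.003 without upstream exposure 2 and 3, 0.092 without entry exposure 2 and 0.135 with exposed RNA in Cy3 alone. Control samples that differed between upstream and the other sites stay open, since the labels do not say which were shared. Noise on upstream arrays widens values without lowering such a slope. The highest slope of a single upstream exposure was 0.144, against 0.7 to 1.111 for the downstream exposures. These slopes cover only the 405 features, so they show that upstream lacked the entry's response. Whether noise hid changes that arose upstream alone stays open. In the first test tried, before the slopes of single exposures were added, the upstream 95% interval reached the entry mean in 1.98% of the 405 with the pooled spread and in 30.9% with the upstream exposures' own spread, so for many single features an upstream change of that size stays open. A response to something in the mine water, copper included, remains a hypothesis and was not tested, since the copper amounts and other water properties were not used here.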

How the results depend on the processing

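The alternatives were planned except the block with both sites alone, the sets of exposures, the tally of largest sizes with exposures left out and the next 19 positive features, which were chosen after seeing the data. The counts of 0 for downstream 1 and downstream 2 against the entry, and between the downstream sites, stayed 0 in limma under all settings that give them, except 1 feature without downstream 2 exposure 3. Upstream against control stayed at 0 except for 163 with exposed RNA in Cy5 alone. Values as deposited, features on all 24 arrays, no filter and a robust spread moved no count by over 1.5 times, though the F test was not run without the filter. Arrays of one dye orientation keep the dye effect, which passed limma's threshold in 56.2% of features and correlated positively in all 66 pairs of exposures. There it can raise calls against control and correlations between sites. Unless said otherwise the cause was not tested.

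Counts are in the order entry, downstream 1 and downstream 2. Scaled arrays gave 152 for downstream 1 against control, 58, 9 and 55 against upstream, and 10 in the F test. All 24 arrays with a dye term and the exposure as a random block gave 699, 477 and 769 against control, 372, 194 and 411 against upstream, 335 in the F test and 376 shared by all mine-water sites. That fit takes one correlation of 0.509 between the arrays of an exposure for all features. Its degrees of freedom count arrays and not exposures, so its higher counts may come partly from that. Array weights gave 726, 653 and 741, then 62, 28 and 32, with 18 in the F test and 342 shared. Exposed RNA in Cy5 alone gave 609, 360 and 836 against control, and 26 and 157 for the downstream sites against upstream. Cy3 alone gave 1217 for downstream 1 against control, 52 and 39 for entry and downstream 2 against upstream, 303 shared, and r = 0.372, 0.467 and 0.307 between upstream and the 3 others (0.287, 0.345 and 0.224 in Cy5 alone). With features on all 24 arrays these were 0.187, 0.188 and 0.004. Fitting only the compared sites gave 0, 9 and 0 against control (968, 1134 and 1074 at an unadjusted p under 0.05), 7, 16 and 25 against upstream, and 0 shared. That fit has 2 residual degrees of freedom for a site and 4 for a pair, fewer by construction than the 8 of the fit of all sites.

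Leaving out 1 exposure, which leaves 2 at its site, gave 144 to 274, 78 to 119 and 157 to 446 against control. Against upstream it gave 14 to 64, 9 to 45 and 11 to 60, in the F test 9 to 48, and 74 to 163 shared. Upstream against control gave 0 to 0, downstream 2 against the entry 0 to 1, and the other pairs of mine-water sites 0 to 0. Correlations ranged from 0.768 to 0.871 for entry and downstream 1, 0.529 to 0.715 for entry and downstream 2, 0.664 to 0.762 for the downstream sites, and -0.06 to 0.278, 0.079 to 0.273 and -0.024 to 0.283 for upstream with the 3 others. The negative ones came without entry exposure 1 and upstream exposure 1.

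With the exposure number as a replicate block, the counts against upstream were 99, 60 and 100, those between mine-water sites 0, and the F test called 38, so none of these counts fell to 0 or rose from it. P9CF4 (3.19) and P13CD12 (-2.26) for downstream 1 against upstream no longer passed under this block, at the same sizes. All same-numbered exposures deviated together only for downstream 2 with upstream and downstream 1 with the entry. With the replicate block and both sites alone these gave 0 and 0 (963 and 349 at an unadjusted p under 0.05), with 2 residual degrees of freedom. Over all sites, deviations of same-numbered exposures correlated over 0.1 in 10 of 18 pairs, the lowest at -0.612, and 7 of 12 exposures had their best partner under their own number. Of 478 values of named features under the alternatives, 385 kept their side of the threshold, 92 no longer passed, 1 newly passed and 0 changed sign where called. In the 92, the size was 70.3% to 116% of the main one (median 100%), and 55 came from leaving out an exposure. Over exposures of different sets the covariance was 0.1148, 0.1045 and 0.1027 among the mine-water sites (0.1369, 0.1363 and 0.1213 averaged over all pairs of exposures). For upstream with the 3 others it was -0.0195, -4e-04 and -0.0068, against 0.0184, 0.0211 and 0.0188, so the sign turned. Finding the sets in the same values lowers it. The gene list tests were not run, since features carry no names. Signal over background is not known here.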

Other observations

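The tests in this part were chosen after the result was seen. All 19 features over 3 on the log2 scale at the entry were also changed at both downstream sites, with entry means from 3.18 to 4.13. They carry 10 different ID prefixes. Their deviations from the site means had a median r of 0.926 between pairs, against 0.115 among the 82 other positive features shared by all mine-water sites. After the mean deviation of the other shared features was removed, the median r was 0.721 among the 19, 0.098 among the 82 and 0.247 among the 19 most negative shared features. No set matched the 19 in size: the negative ones had entry means from -1.54 to -2.41, and the next 19 positive ones, from 1.43 to 2.99, gave 0.139. Larger responses alone may raise such an r, and this was not separated. Not all of them moved alike. The lowest r of a pair was -0.106, and 17 of the 19 had a median r over 0.5 with the others, while P4CB5 had 0.36. In upstream exposure 3, whose arrays agreed least, the 19 ranged from 0.02 to 2.14, with P4CB5 the highest. Some of these features may be clones of one transcript, which the median of 0.721 would allow, but this stays open for all of them. Transcripts of related genes that bind each other's spots, and genes regulated together, stay open too, because clone sequences were not used here. If the hypothesis holds, the number of changed features overstates the number of changed genes.

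Changed features at the entry were spread unevenly over the 20 ID prefixes, by a permutation test of 10000 shuffles for negative and for positive calls (p 1e-04 each, the smallest these shuffles can give). The shuffles treat features as independent. Features that move together, or clones of one transcript under one prefix, would make this p too small. Prefix A6 had 27 negative calls among 380 features (7.11%), against 2.6% among all other features. Of these 27, 20 were also negative calls at downstream 1 and 25 at downstream 2. The A6 features that did not change had a median of -0.089. Those of A7, A5 and A4 lay lower, at -0.283, -0.171 and -0.165, with 1.07%, 0.824% and 0.794% negative calls, so this median does not set A6 apart. The mean r of deviations between the A6 negative calls was 0.275, against 0.281 for pairs from other prefixes. Of features whose ID starts with A, 3.22% changed at the entry, against 6.6% of those starting with P.

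Of the 174 shared features, 104 had their largest size at the entry, 52 at downstream 2 and 18 at downstream 1. This tally depended on single exposures. It was 74, 71 and 29 without entry exposure 2, 76, 42 and 56 without downstream 1 exposure 1, and 81, 71 and 22 without downstream 2 exposure 2. The median sizes were 1.23, 1.09 and 1.07. A6E16 had the lowest adjusted p in limma at all 3 mine-water sites (6e-06, 1e-06 and 3.4e-07), and was at 0.02 ± 0.03 upstream (SD, n = 3).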
